A study of Mus musculus with 39 samples.

How the data were processed

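Per the labels' protocols, total RNA was extracted with Trizol, and mRNA was enriched and fragmented. cDNA libraries were amplified by PCR and sequenced on an Illumina platform. How pancreatitis was induced, when tissue was taken, whether the library kit marked strand and whether lung and colon came from the same animals are not given in the sources used here. HISAT2 2.1.0, StringTie 1.3.3b and the mm39 build are named in the submitters' processing notes, without their roles. The annotation, any trimming and any filter on reads are not given either.

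The deposited values are FPKM, fragment counts scaled by the authors to gene length and library total, in one table per tissue with a column per library and an Ensembl gene per line. Each table held 55357 genes, of which 52081 had a symbol in the table of gene names used. The values of a gene in different libraries stood in ratios of small whole numbers, which gave the library totals. With these totals 99.1% of the 7706 lung genes with a single transcript, and 99.0% of the 6690 colon genes, came out as whole reads within 0.01 read. For genes with several transcripts the shares were 14.9% of 7378 and 14.6% of 7988, so counts could not be recovered for all genes and no count test was run.

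Samples were grouped by the tissue, genotype and treatment in the labels, and all 39 were used. Each tissue was analysed alone, since each table was made separately. Genes with at least 1 FPKM in at least 4 libraries of a tissue were tested, 15978 in lung and 15001 in colon. Values were taken as log2(FPKM + 1), a scale that understates the change of genes with low values. A linear model with 1 mean for each of the 4 groups was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the expression level. The 5 comparisons were AP against sham in WT and in KO, KO against WT in AP and in sham, and the difference between the AP responses of the genotypes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed, without a minimum fold. Cd177 was compared by exact two-sided permutation tests of the FPKM. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

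Gene lists were written from general knowledge of the tissues, 27 for lung and 29 for colon and 35 in all. The lists for both tissues covered mature neutrophils, neutrophil granule precursors, inflammatory cytokines, acute phase proteins, endothelial activation, interferon-stimulated, glucocorticoid-responsive, circadian, immediate early, fasting, cell cycle and unfolded protein response genes, hemoglobin, mitochondrially encoded genes, and markers of T and NK cells, B and plasma cells, macrophages, endothelium, matrix and fibroblasts, adipocytes and pancreatic acinar cells. Lung also had alveolar type 1 and type 2, alveolar macrophage, club and ciliated, junction and cardiac muscle genes. Colon also had goblet, absorptive colonocyte, stem cell, enteroendocrine and tuft, antimicrobial, junction, smooth muscle and enteric neuron genes. Lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, with Benjamini-Hochberg adjustment over the lists of a tissue, given as the camera FDR. A list needed 3 measured genes, which left 26 in lung, without acinar genes. Camera was repeated with the correlation estimated from the data. List members were counted as passing over all genes tested and adjusted over the list alone.

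The groups, comparisons, tests, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Cd177, Pecam1, Mpo, Elane and Padi4 were always named. For AP against sham in WT and for KO against WT in AP, the 8 largest rises and 8 largest falls were named among genes past the threshold with a mean of at least 2 FPKM in a group compared. For the other comparisons 5 of each were named. Where fewer than 5 genes passed, the 5 with the lowest p were named, and each list gave up to 4 members with the lowest p. Predicted genes, pseudogenes, antigen receptor segments and genes without a symbol were left out of this ranking. So were symbols made of a clone or sequence accession, a choice made after the data were seen. Some genes that this rule would name are not reported here.

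The procedure was tested on simulated libraries with the means and within-group spread of these genes and 200 changed genes per comparison. At a 2-fold change it recovered 80% in lung for AP against sham in WT, 84% in KO, 87% for KO against WT in AP and 82% in sham. In colon the shares were 72%, 70%, 80% and 71% in the same order. Of 15678 unchanged lung genes 6, 191, 38 and 72 were called, and of 14701 unchanged colon genes 12, 94, 67 and 25. The numbers for comparisons with KO groups, foremost AP against sham in KO, were higher than a threshold of 0.05 allows. Each simulated group kept its own spread, while the model uses one variance for all groups. All 5 shifted lists and no unshifted list were called in each comparison. Other groupings of the real libraries called medians of 8 to 11 lists, so the simulation does not bound false list calls.

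Alternatives were a pseudocount of 0.1, no filter on low values, a filter of 5 FPKM, upper quartile scaling, a TPM scale, the replicate number as a block, limma's arrayWeights, a fit of only the compared groups, a minimum of 2-fold, an estimated correlation and leaving out each library in turn. A correction for transcript length and the omission of libraries with a mean correlation under 0.94 with their own group were added after the data were seen. Transcript lengths came from GENCODE M21, an annotation of an earlier mouse build. It covered 99.4% of tested lung and 99.6% of tested colon genes and gave the gene order around Cd177. For each count, 100 splits of the libraries were compared, the real one included.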

Results

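Gene expression was measured by sequencing mRNA-enriched RNA in lung and colon of C57BL/6N mice. The mice were wild type (WT) or lacked Cd177 (KO), a gene for a surface protein of neutrophils, and had either a sham operation or acute pancreatitis (AP), an inflammation of the pancreas that can injure distant organs. There were 39 libraries, 5 in each of the 8 groups of tissue, genotype and treatment but 4 in KO colon with AP. The labels do not say whether each is from a separate animal, so limma and permutation p measure the spread between libraries. The camera FDR compares a list with other genes instead.

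The read totals recovered from the steps of the deposited values lay between 57.9 and 71.2 M reads in the WT lung libraries and between 77.0 and 95.4 M reads in the KO lung libraries (M, the metric prefix mega). In the colon they lay between 55.6 and 78.3 M reads in WT and between 77.7 and 98.6 M reads in KO. None of the 10 KO lung libraries, and 1 of the 9 KO colon libraries, had a total below the highest WT total of its tissue. On average 25264 genes had a value above 0 in WT lung and 23657 in KO lung, against 24075 in WT colon and 22760 in KO colon. The first principal component separated the genotypes completely and held 58.2% of the variance in lung and 37.9% in colon. Libraries resembled their own group less in KO than in WT lung, with mean correlations of 0.929 to 0.962 against 0.968 to 0.988. The range in colon was 0.934 to 0.954 in KO and 0.942 to 0.975 in WT. Mitochondrially encoded genes took from 2.49% to 14.0% of the FPKM of a lung library and from 4.62% to 19.1% of that of a colon library. Log2 changes correlated across genes with transcript length, with a Spearman coefficient of -0.359 for KO against WT in lung AP and -0.461 in lung sham. In colon this coefficient was -0.057 in AP and -0.342 in sham. For AP against sham it was -0.343 in WT lung, 0.112 in KO lung, -0.347 in WT colon and 0.255 in KO colon; genes are not independent replicates.

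Cd177 was present in every WT library and listed at 0 in every KO library of both tissues. In lung it was 2.01 ± 0.926 FPKM in WT sham and 3.19 ± 0.926 FPKM in WT AP (mean ± SD, n = 5 each), with single libraries from 1.3 to 3.59 and from 2.1 to 4.18. In colon it was far more abundant, at 43.2 ± 5.6 FPKM in WT sham and 60.7 ± 11.5 FPKM in WT AP (n = 5 each), with single libraries from 38.5 to 52.1 and from 49.7 to 76.4. KO and WT differed in each tissue and treatment at an exact two-sided permutation p of 0.00794, the smallest these group sizes allow. In WT colon Cd177 was higher by 17.5 FPKM with AP in this test of the gene alone (exact two-sided permutation p = 0.0238), but it did not pass over all genes (limma log2 0.47 ± 0.12, adjusted p = 0.791). In WT lung the difference of 1.18 FPKM did not pass (exact two-sided permutation p = 0.0714), but it was 1.45 FPKM without WT AP replicate 1 (exact p = 0.0476) and 1.57 FPKM without WT sham replicate 1 (exact p = 0.0317). Actb, Gapdh, Eef1a1, Ppia, Rplp0, B2m, Hprt and Tbp were at 0 in no library.

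**Figure D1:**
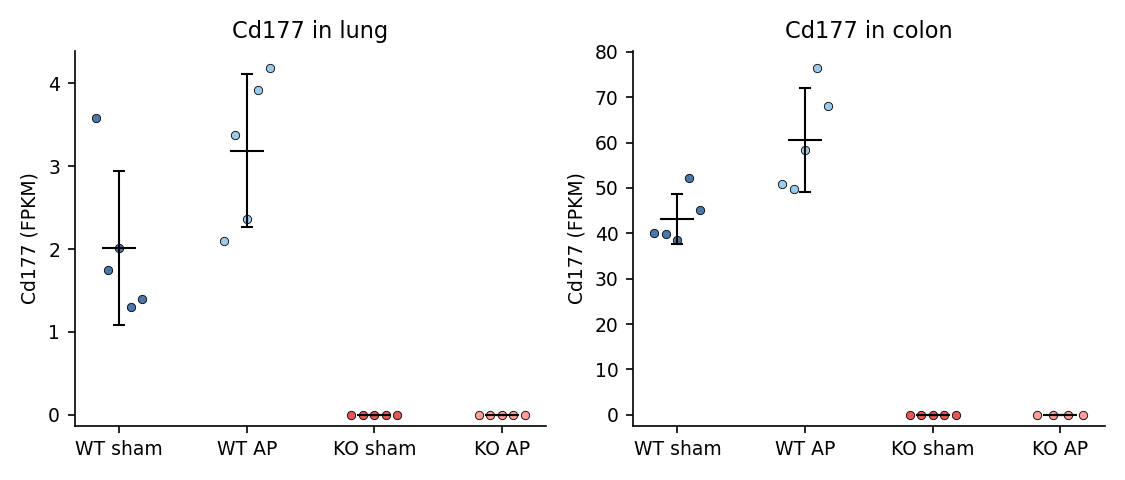
Cd177 in FPKM (vertical axis) in each library of the 4 groups of lung (left) and colon (right); points are libraries and bars are the group mean ± SD. Every KO library sits at 0 and every WT library above it.

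In WT lung with pancreatitis 3 circadian clock genes passed the threshold, although their list was not called. Dbp, a transcription factor driven by the clock, rose from 7.12 ± 6.42 FPKM in sham to 55.6 ± 19.9 FPKM in AP (mean ± SD, n = 5 each), a log2 change of 3.07 ± 0.50 (SE; adjusted p = 0.0268, limma). Arntl, which encodes the clock activator BMAL, fell by 1.33 ± 0.22 and Nfil3 fell by 1.3 ± 0.23 on the log2 scale. Cdkn1a fell from 222 ± 47.7 to 68.0 ± 25.4 FPKM, a log2 change of -1.75 ± 0.26 (adjusted p = 0.0250).

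In all, 13 of the 15978 genes tested changed in WT lung, 4 up and 9 down (limma). The other rises were Clec12a at 0.78 ± 0.13, Id2 at 0.69 ± 0.12, and Cks2 at 0.60 ± 0.11. Further falls were Tnfrsf10b at -1.12 ± 0.20, Nos1ap at -0.90 ± 0.15, Cerk at -0.79 ± 0.13, Plekha8 at -0.67 ± 0.13 and Dusp16 at -0.63 ± 0.11. The endothelial gene Pecam1 was at 284 ± 17.7 FPKM in sham and 247 ± 26.8 FPKM in AP (adjusted p = 0.934). Padi4, which citrullinates histones in neutrophils, was at 2.03 ± 0.900 and 2.29 ± 0.539 FPKM (adjusted p = 0.971). The granule genes Mpo and Elane averaged 0.303 and 0.196 FPKM in WT sham and were too low to be tested in either tissue.

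Of the 26 gene lists that could be tested in lung, 13 were called in WT AP against sham by camera with a preset correlation (FDR, its adjusted p). Cell cycle genes were higher, with a median log2 change of 0.52 over 19 genes (camera FDR = 1.74e-14; 0.235 with an estimated correlation). None of them passed over all genes, and 9 were higher when adjusted over the list alone, among them Birc5 at 0.80 ± 0.24 and Pclaf at 0.83 ± 0.26. Glucocorticoid-responsive genes were lower, with a median of -0.60 over 17 genes (camera FDR = 8.58e-12; 0.180 with an estimated correlation). Cdkn1a was the only member to pass over all genes, and 7 were lower over the list alone, including Ddit4 at -1.29 ± 0.35 and Dusp1 at -0.84 ± 0.27.

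Leukocyte lists shifted upward in WT lung without any member passing over all genes or over its list alone. The median log2 change was 0.82 for mature neutrophil genes (camera FDR = 1.11e-07), 0.56 for B and plasma cell markers (camera FDR = 2.78e-08), 0.40 for T and NK cell markers (camera FDR = 1.08e-05) and 0.39 for monocyte and macrophage markers (camera FDR = 1.44e-05). Interferon-stimulated genes had a median of 0.44 (camera FDR = 7.90e-05). With an estimated correlation these 5 lists had adjusted p = 0.50, 0.382, 0.636, 0.475 and 0.636. S100a8, a neutrophil alarmin, was at 1.69 ± 0.68, Ncr1 at 0.87 ± 0.26, and Ccr2 at 0.79 ± 0.24, none passing.

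Circadian genes moved both ways in WT lung, with 1 of 17 up and 2 down over all genes, and 7 up and 5 down over the list alone. Their median was -0.07 and their mean 0.12, and camera gave no call (adjusted p = 0.816; 0.941 with an estimated correlation). The other 6 calls each ended when a single library was left out. Mitochondrially encoded genes (median 0.27, camera FDR = 0.0116) missed without WT AP replicate 4 (0.722) or WT sham replicate 1 (0.106). Club and ciliated cell markers (median 0.23, camera FDR = 0.0209) missed without WT AP replicate 4 (0.0804) or WT sham replicate 4 (0.0631). Cardiac muscle markers (median 0.50, camera FDR = 0.0277) missed without WT AP replicate 1 (0.132) or 4 (0.0720) or WT sham replicate 4 (0.155) or 5 (0.050007), and after upper quartile scaling (0.0618). Fasting genes (median -0.13, camera FDR = 0.0306) missed without WT AP replicate 3 (0.0774) or 4 (0.0720) or WT sham replicate 1 (0.149), and immediate early genes (median -0.20, camera FDR = 0.0103) without WT sham replicate 1 (0.325). Neutrophil granule precursor genes (median 0.28, camera FDR = 0.0499) missed in 13 of 20 omissions, at most 0.153 without WT AP replicate 5, and after upper quartile scaling (0.0909). With an estimated correlation these 6 lists had adjusted p = 0.686, 0.475, 0.686, 0.686, 0.636 and 0.636.

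The count of 13 genes also rested on single libraries. It was 0 without WT AP replicate 3 or 4 or WT sham replicate 2 or 3, 1 without WT AP replicate 1 or WT sham replicate 4, 2 without WT AP replicate 5, 4 without WT AP replicate 2, 5 without WT sham replicate 1 and 20 without KO AP replicate 3. Of the 20 omissions, Dbp missed in 8, with the highest adjusted p of 0.127 without WT sham replicate 2, and Cdkn1a missed without WT AP replicate 3 (0.0975) or 4 (0.0526) or WT sham replicate 2 (0.0721) or 3 (0.0634).

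**Figure D2:**
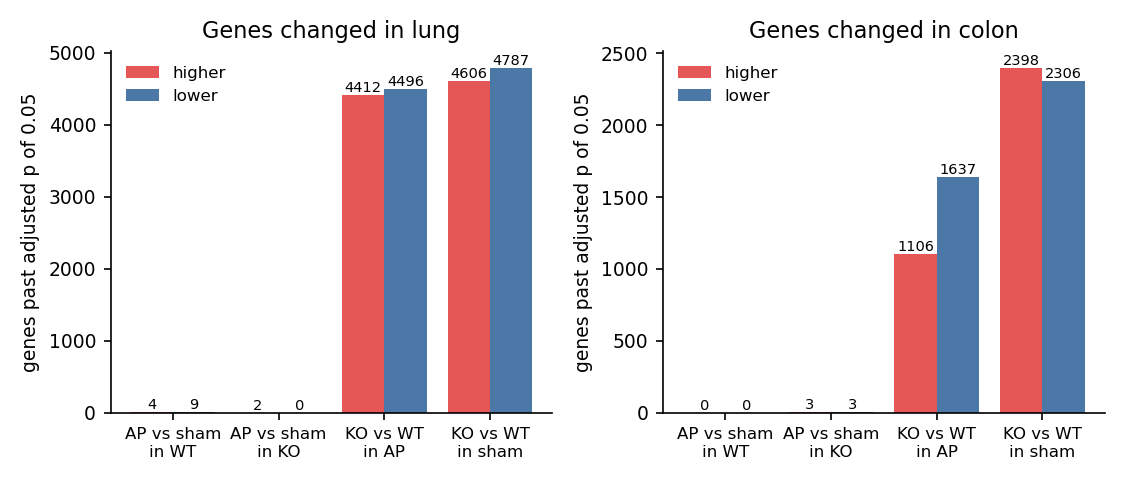
Genes changed up and down by limma at an adjusted p under 0.05 in 4 comparisons of lung (left) and colon (right), with the number of genes on the vertical axis. KO against WT gave 2743 or more calls in each tissue and treatment, while AP against sham gave 13 or fewer in either genotype.

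Pancreatitis in KO lung changed 2 genes, both up (limma; 2234 genes had an unadjusted p under 0.05). Itprid1 rose from 1.38 ± 0.351 to 4.31 ± 1.58 FPKM (n = 5 each), a log2 change of 1.12 ± 0.17 (adjusted p = 0.0121). The second gene, Gm9747, a predicted gene named after its values were seen, rose with an adjusted p of 0.00254. Among the genes with the lowest p that did not pass were Agmo at 0.63 ± 0.11 (adjusted p = 0.0544), Ky at 0.82 ± 0.15 (adjusted p = 0.0576) and Chad at 1.52 ± 0.28 (adjusted p = 0.0576). Pecam1 was at 117 ± 46.1 FPKM in KO sham and 83.1 ± 15.1 FPKM in KO AP (adjusted p = 0.416), and Padi4 at 2.37 ± 2.17 and 1.5 ± 0.906 FPKM (adjusted p = 0.632).

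Airway epithelial genes were higher in KO lung with AP. Club and ciliated cell markers had a median log2 change of 0.78 over 14 genes (camera FDR = 4.24e-07), and this was the single list call of either tissue to hold with an estimated correlation (adjusted p = 0.0427). No member passed over all genes, and 4 were higher over the list alone, including Scgb3a2 at 1.18 ± 0.29 and Dnah5 at 0.79 ± 0.21. Matrix and fibroblast markers were lower, with a median of -0.51 over 19 genes and 11 lower over the list alone, none over all genes (camera FDR = 4.24e-07; 0.242 with an estimated correlation). Timp1 was at -1.64 ± 0.35 (adjusted p = 0.0849) and Col3a1 at -1.03 ± 0.25 (adjusted p = 0.127).

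Several immune and stress lists were lower in KO lung with AP. The median was -0.65 for T and NK cell markers (camera FDR = 1.83e-06), -0.53 for monocyte and macrophage markers (camera FDR = 9.91e-05), -0.49 for unfolded protein response genes (camera FDR = 2.88e-05), -0.39 for acute phase proteins (camera FDR = 0.00731) and -0.52 for interferon-stimulated genes (camera FDR = 0.00435). With an estimated correlation these had adjusted p = 0.378 for the first 4 and 0.527 for the interferon list. Adjusted over the list alone, 7 monocyte and macrophage markers were lower, including C1qa at -0.76 ± 0.22, and no member of these lists passed over all genes. Circadian genes (median 0.26) and immediate early genes (median 0.17) were higher, at camera FDR of 0.00731 and 0.0229 and at adjusted p = 0.336 and 0.432 with an estimated correlation.

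These calls, with that of inflammatory cytokines (median -0.29, camera FDR = 0.0283; 0.382 with an estimated correlation), also passed without the 3 libraries whose correlation with their own group was under 0.94, KO AP replicate 3 and KO sham replicates 4 and 5. The other 13 calls of the 23 in this comparison did not. Those were hemoglobin (median -1.19), cardiac muscle (1.25), mitochondrially encoded (0.57), fasting (0.40), adipocyte (0.66), alveolar macrophage (-0.49), endothelial activation (-0.34), glucocorticoid-responsive (-0.34), alveolar type 1 (-0.25), alveolar type 2 (-0.27), endothelial (-0.25), B and plasma cell (-0.34) and mature neutrophil (-0.56) genes, with adjusted p from 0.336 to 0.542 with an estimated correlation. Their camera FDR lay between 5.35e-05 and 0.0435 with all libraries and between 0.0736 and 0.989 without these. Without these libraries the median of the neutrophil list was 0.06, that of B and plasma cell markers 0.18, that of endothelial markers 0.11, that of alveolar type 1 markers 0.01 and that of adipocyte markers -0.39, opposite in sign to the values with them. Without KO sham replicate 4, 15 lists were called. The interferon call ended without KO AP replicate 1 or 5 or KO sham replicate 2 or 3, at camera FDR of 0.0530, 0.0589, 0.128 and 0.118. The cytokine call ended without KO AP replicate 2 or 5 or KO sham replicate 1, 2 or 4, at 0.109, 0.0992, 0.0539, 0.112 and 0.127, and that of immediate early genes without KO AP replicate 1, 4 or 5 or KO sham replicate 3, at 0.0662, 0.0596, 0.176 and 0.0689. Of the 13 calls, those of endothelial activation (0.0507) and alveolar type 1 genes (0.210) also ended without KO sham replicate 4 alone, and that of glucocorticoid genes without KO AP replicate 1 (0.0662) or 3 (0.0545). Mature neutrophil, B and plasma cell and adipocyte genes missed in 4 omissions each, at most 0.722 and 0.373 without KO sham replicate 4 and 0.149 without KO AP replicate 3 (median -0.34). Endothelial and alveolar type 2 genes missed in 7 and 6, at most 0.698 and 0.689 without KO sham replicate 4 and 5. The cardiac muscle median was 0.53 without KO AP replicate 3, and 1.94 and 1.84 without KO AP and KO sham replicate 5.

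The number of genes changed in KO lung was 1 without KO AP replicate 4, 5 without KO sham replicate 5, 22 without KO sham replicate 3, 26 without KO AP replicate 1, 134 without KO AP replicate 3 and 229 without KO sham replicate 1. Itprid1 missed without KO AP replicate 4 (adjusted p = 0.0646). Agmo, Ky and Chad passed without KO AP replicate 1 or 3 or KO sham replicate 1, at adjusted p from 0.0163 to 0.0367. Without KO sham replicate 3, Agmo (0.0168) and Chad (0.0317) passed, as did Agmo without WT sham replicate 3 (0.0364). Without KO sham replicate 1, Pecam1 (0.0481), Col3a1 (0.0471), C1qa (0.0467) and Dnah5 (0.0367) passed, as did Scgb3a2 without KO AP replicate 3 (0.0329). Timp1 passed without KO AP replicate 1 (0.0316) or 3 (0.0472) or KO sham replicate 1 (0.0497) or 3 (0.0365).

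KO and WT lungs differed broadly in pancreatitis, the central comparison. Gsta1, a glutathione transferase, was at 135 ± 109 FPKM in KO against 0.444 ± 0.195 FPKM in WT (n = 5 each), a log2 difference of 6.17 ± 1.06 (adjusted p = 9.13e-05, limma). Gsta1 and its close relative Gsta2, at 3.58 ± 0.59, may share reads, so their separate levels are uncertain. Retnla was at 757 ± 337 FPKM in KO and 79.5 ± 19.97 FPKM in WT. The endothelial and lymphatic gene Lyve1 was lower in KO, at 29.9 ± 9.10 against 224 ± 59.4 FPKM (log2 -2.86 ± 0.35, adjusted p = 3.34e-06), and Pecam1 was at 83.1 ± 15.1 against 247 ± 26.8 FPKM (log2 -1.57 ± 0.22, adjusted p = 1.37e-05).

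Other large rises were Uchl1 at 4.03 ± 0.65, Cldn4 at 3.50 ± 0.76, Ces1g at 3.48 ± 0.48, Fbxo2 at 2.78 ± 0.42 and Slc7a11 at 2.74 ± 0.69. The largest falls were Ston1 from 31.0 ± 12.6 to 1.06 ± 0.840 FPKM (-3.92 ± 0.32), and Ccl5, a chemokine of T and NK cells, from 159 ± 89.1 to 10.5 ± 8.26 FPKM (-3.85 ± 0.57). The cell adhesion genes Vcl and Itga6 fell by 3.50 ± 0.34 and 2.99 ± 0.60 (3.61 for Itga6 without KO AP replicate 4), Lrch3 fell by 2.88 ± 0.20, and Hyal1 fell by 2.88 ± 0.30. Padi4 did not pass, at -0.44 ± 0.29 (adjusted p = 0.208).

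In this comparison 8908 of 15978 genes changed, 4412 higher and 4496 lower in KO, and 2298 of them by at least 2-fold. On a TPM scale 8457 changed, 2965 higher and 5492 lower, and the median of all genes moved to -0.182, so the split between directions depends on the scaling.

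Markers of many lung cell types were lower in KO with AP. T and NK cell markers were lower in 20 of 20 genes, with a median of -1.75 (camera FDR = 1.17e-07). Cd4 was at -1.35 ± 0.19, Cd3e at -2.16 ± 0.32 and Cd28 at -1.28 ± 0.19. Matrix and fibroblast markers were lower in 13 of 19 genes and higher in 1 (median -0.89, camera FDR = 0.000451), with Dpt at -2.1 ± 0.23 and Pdgfra at -1.78 ± 0.22. Endothelial markers were lower in 10 of 18 and higher in 1 (median -0.71), alveolar type 1 markers lower in 10 of 14 and higher in 1 (median -0.83), alveolar type 2 markers in 10 of 15 (median -0.80) and alveolar macrophage markers in 12 of 14 (median -1.02), all at a camera FDR of 0.00353. Examples were Cdh5 at -2.42 ± 0.28, Emp2 at -1.71 ± 0.18, Abca3 at -1.09 ± 0.14 and Ear1 at -2.62 ± 0.41. Each of these 6 lists had an adjusted p = 0.683 with an estimated correlation.

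B and plasma cell markers were lower in 9 of 18 genes over all genes and over the list alone (median -0.92, camera FDR = 0.00702), and monocyte and macrophage markers in 9 of 19 with 1 higher, Cd14, at 1.83 ± 0.23 (median -0.79, camera FDR = 0.0181). Hemoglobin and erythroid genes were lower in 5 of 6, and 6 over the list alone (median -1.86, camera FDR = 0.0352), with Hbb-bt at -2.67 ± 0.59 and Hbb-bs at -2.39 ± 0.57, near-identical genes whose separate levels are uncertain. This call ended on a TPM scale (camera FDR = 0.0558), and without WT AP replicate 2 (0.0577), KO AP replicate 4 (0.0548) or KO AP replicate 5 (0.0624). Immediate early genes were higher in 11 of 19 and lower in 2 (median 0.63, camera FDR = 0.00756), led by Jund at 1.31 ± 0.13 and Egr1 at 1.89 ± 0.23. Unfolded protein response genes were higher in 5 of 16 (median 0.42, camera FDR = 0.0328), with Atf4 at 0.99 ± 0.20 and Asns at 1.65 ± 0.34. Their call ended without WT AP replicate 4 (camera FDR = 0.0516), KO AP replicate 1 (0.0733) or KO AP replicate 3 (0.0690). With an estimated correlation each of these 5 lists had an adjusted p = 0.683.

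Lung junction and fluid transport genes went both ways, with 6 higher and 8 lower of 19 over all genes and over the list alone (median -0.23, camera FDR = 0.434), Tjp1 at -1.71 ± 0.18 among them. Circadian genes were higher in 6 and lower in 3 of 17 (camera FDR = 0.349), with Clock at -0.52 ± 0.10. Endothelial activation genes (8 of 13 lower, median -0.47) and mature neutrophil genes (3 higher and 4 lower of 22, median -0.50) were not called, at camera FDR of 0.0954 and 0.468. Inflammatory cytokines (4 higher and 5 lower of 16) had a median of -0.08 and a mean of 0.02 (camera FDR = 0.768). Interferon-stimulated genes (3 of 20 lower, median -0.75, camera FDR = 0.120) were called without KO AP replicate 3 (0.00256) or WT AP replicate 4 (0.0315).

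**Figure D3:**
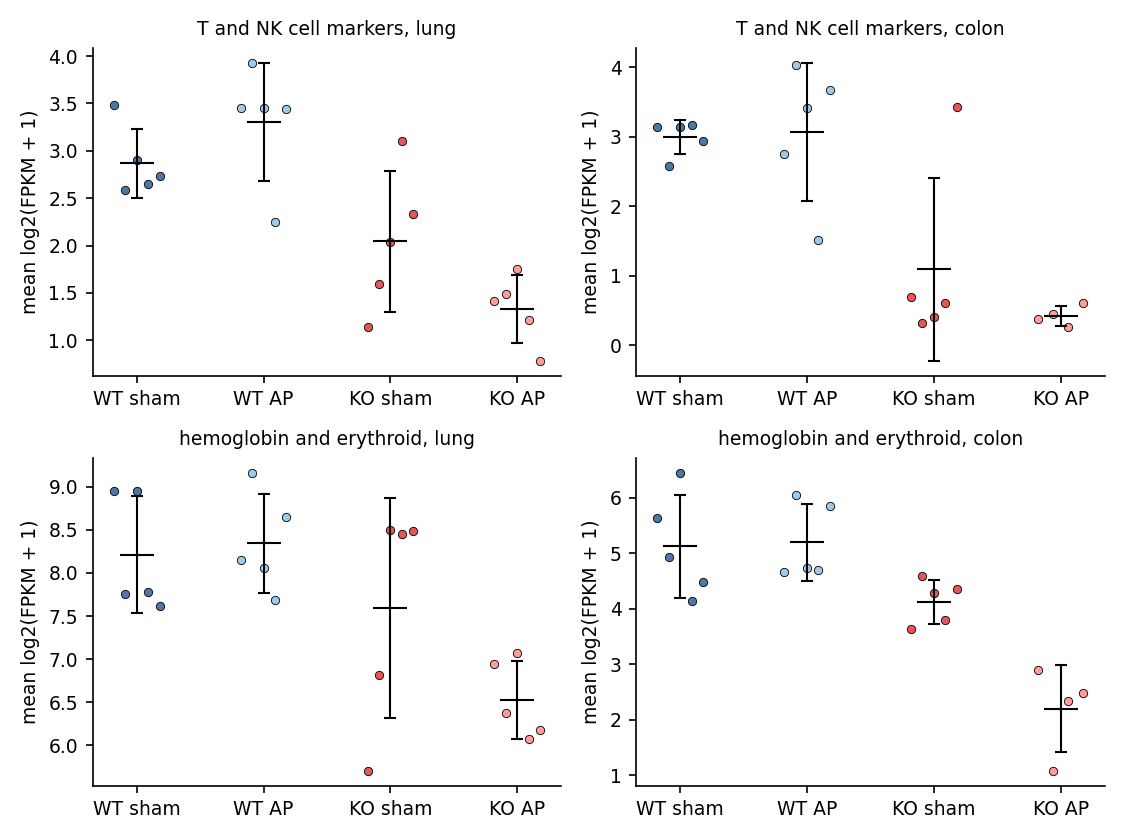
Mean log2(FPKM + 1) of T and NK cell markers (top) and of hemoglobin and erythroid genes (bottom) in each library of lung (left) and colon (right), by group; points are libraries and bars are the group mean ± SD. In colon the T and NK cell markers lie below every WT library in all KO libraries but KO sham replicate 5, at 3.44.

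KO and WT lungs differed as broadly after sham operation as in pancreatitis. Gsta1 was at 289 ± 213 FPKM in KO sham and 0.463 ± 0.119 FPKM in WT sham (n = 5 each), a log2 difference of 6.30 ± 1.06 (adjusted p = 5.69e-05, limma). Cldn4 was higher at 4.08 ± 0.76, Uchl1 at 4.04 ± 0.65, Sprr1a at 3.93 ± 0.56 and Gsta2 at 3.86 ± 0.59. Ston1 fell by 4.34 ± 0.32, Mfsd4a fell by 3.48 ± 0.44, Zbtb16 fell by 3.45 ± 0.56 and Vcl fell by 3.43 ± 0.34. Gsta1, Cldn4, Uchl1 and Gsta2 were at 7.83, 4.99, 4.93 and 4.68 without KO sham replicate 4, and Cldn4 at 3.38 without KO sham replicate 1. Pecam1 was lower in KO, at 117 ± 46.1 against 284 ± 17.7 FPKM (log2 -1.38 ± 0.22, adjusted p = 3.59e-05), and Padi4 did not pass at 0.02 ± 0.29 (adjusted p = 0.954).

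Of 15978 genes, 9393 changed in lung sham, 4606 higher and 4787 lower, with 2582 changed at least 2-fold. On a TPM scale 9100 changed, 2891 higher and 6209 lower, with the median of all genes at -0.256. Of the genes higher in KO with AP, 3513 were also higher in sham, where independent lists of these sizes would share 1272. Of those lower, 3669 were shared, against 1347 for independent lists. The log2 differences in AP and sham correlated across genes at a Pearson r of 0.876, and the pair of comparisons shares no library.

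Unfolded protein response genes were the leading list in lung sham, higher in 13 of 16 genes (median 1.07, camera FDR = 0.00370). Manf was at 1.78 ± 0.27, Asns at 2.08 ± 0.34 and Creld2 at 1.38 ± 0.23. Fasting genes were lower in 12 of 17 and higher in 1 (median -0.58, camera FDR = 0.0176), with Cpt1a at -1.73 ± 0.12. Endothelial markers were lower in 8 of 18 with 1 higher (median -0.51) and T and NK cell markers in 11 of 20 (median -0.85), both at a camera FDR of 0.0289, and alveolar type 2 markers in 9 of 15 (median -0.88, camera FDR = 0.0494). All 5 lists had an adjusted p = 0.933 with an estimated correlation.

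The last 3 calls rested on single libraries. Without KO sham replicate 1 the camera FDR was 0.0867 for endothelial, 0.10 for T and NK cell and 0.102 for alveolar type 2 markers, and without KO sham replicate 2 it was 0.0535, 0.0545 and 0.0610. T and NK cell markers also missed without WT sham replicate 1 (0.0637), and alveolar type 2 markers without any of 11 libraries in all, at 0.0508 to 0.102. In all 5 lists were called, 3 without KO sham replicate 1 and 2 without KO sham replicate 2. Mature neutrophil genes were higher in 6 of 22 (median 0.64, camera FDR = 0.0846), called without KO sham replicate 1 (0.00830) or 3 (0.0442), but the median was -0.16 without the low-correlation libraries named above. Glucocorticoid genes were lower in 9 of 17 and higher in 3 (camera FDR = 0.0619), called without WT AP replicate 5 (0.0449), KO AP replicate 5 (0.0475), KO sham replicate 3 (0.0465) or WT sham replicate 4 (0.0310), and acute phase proteins (2 higher and 4 lower of 15) had a median of -0.04 and a mean of 0.01.

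The interaction in lung asked whether the response to pancreatitis differed by genotype, and no gene passed (limma; 1384 genes had an unadjusted p under 0.05). The lowest p belonged to Kcnj13 at 1.43 ± 0.24 (adjusted p = 0.103), and to Arntl at 1.71 ± 0.32 (adjusted p = 0.125). Clec12a followed at -0.94 ± 0.19 and Agmo at 0.80 ± 0.16 (adjusted p = 0.184 each), with Kyat1 at 0.62 ± 0.13 (adjusted p = 0.233). Pecam1 was at -0.19 ± 0.31 and Padi4 at -0.47 ± 0.42. Leaving out a single library gave 1 gene without KO AP replicate 3 or WT sham replicate 1 and 2 without KO sham replicate 2. Kcnj13 passed without KO AP replicate 3 (adjusted p = 0.00770).

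In lung the interaction called 16 of 26 lists, led by T and NK cell markers with a median of -1.12 (camera FDR = 4.03e-11), monocyte and macrophage markers with -0.73 (3.58e-09) and cell cycle genes with -0.55 (6.93e-09), each with an adjusted p = 0.234 with an estimated correlation. No member passed over all genes, and 2, 6 and 1 were lower over the list alone, among them Ncr1 at -1.36 ± 0.36, C1qa at -1.34 ± 0.31 and Birc5 at -1.26 ± 0.34. Hemoglobin genes moved with them (median -1.31, camera FDR = 0.00270), and KO sham replicate 4 had a T and NK mean of 3.11 and a mature neutrophil mean of 5.62, against at most 2.34 and 4.44 in the rest of its group. Across genes the responses to AP in WT and KO lung correlated at a Pearson r of 0.0276, which was -0.0687 without WT AP replicate 4, -0.0527 without KO AP replicate 3, -0.0249 without KO sham replicate 3 and -0.0156 without KO sham replicate 4.

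In WT colon pancreatitis changed no gene of 15001 (limma; 938 genes had an unadjusted p under 0.05). The genes with the lowest p were Nufip2 at -0.52 ± 0.09 (adjusted p = 0.227), Bora at 0.79 ± 0.17 and Slc10a5 at -0.87 ± 0.19 (adjusted p = 0.685 each), Atp7a at -0.78 ± 0.17 (adjusted p = 0.774) and Camsap2 at -0.83 ± 0.19 (adjusted p = 0.791). Pecam1 was at 13.3 ± 1.96 FPKM in sham and 11.1 ± 2.44 FPKM in AP, without passing (limma, n = 5 each). Padi4, too low to be tested, averaged 0.111 and 0.184 FPKM, Mpo 0.0297 and 0.0366 FPKM, and Elane 0.0220 and 0.00622 FPKM. Without WT sham replicate 4 the count was 1.

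Cell cycle, fasting and glucocorticoid lists were called in WT colon with AP at the preset correlation of camera alone. Cell cycle genes had a median of 0.56 over 20 genes, with none passing over all genes or over the list alone (camera FDR = 1.04e-08). Fasting genes had a median of -0.30, with 4 lower over the list alone (camera FDR = 4.14e-08), including Angptl4 at -0.56 ± 0.16 and Pdk4 at -1.15 ± 0.35. Glucocorticoid genes had a median of -0.25, with 5 lower over the list alone (camera FDR = 3.46e-06), including Zbtb16 at -1.3 ± 0.34 and Sgk1 at -1.14 ± 0.30. These 3 lists had adjusted p = 0.782, 0.228 and 0.161 with an estimated correlation. Circadian genes were not called (median 0.05, camera FDR = 0.826), and 2 were higher over the list alone, Dbp at 1.62 ± 0.44 and Nr1d1 at 1.45 ± 0.38.

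The other 3 of the 6 calls were lost without WT sham replicate 2. Endothelial markers (median -0.21) then had a camera FDR of 0.0589, smooth muscle markers (median -0.24) of 0.114 and absorptive colonocyte markers (median -0.21) of 0.971. Their calls with all libraries had camera FDR of 0.00517, 0.0199 and 0.0376, and adjusted p = 0.782, 0.918 and 0.918 with an estimated correlation. The endothelial call also ended without WT AP replicate 5 (0.0742), that of smooth muscle without WT AP replicate 5 (0.932) or WT sham replicate 5 (0.0839), and that of colonocytes without WT AP replicate 2 (0.195) or 3 (0.0536). Further lists were called without 1 library, and antimicrobial genes were higher on a TPM scale (0.0378). Mature neutrophil (0.0137), cytokine (0.00309) and T and NK cell genes (0.00353) were higher without WT AP replicate 4, B and plasma cell markers without WT AP replicate 1 (0.000167) or WT sham replicate 4 (0.00437), and unfolded protein response genes without WT AP replicate 2 (0.0478) or WT sham replicate 5 (0.0220). Enteric neuron markers were lower without WT AP replicate 1 (0.0118), and adipocyte markers without WT AP replicate 3 (0.0159) or WT sham replicate 1 (0.0271), 3 (0.0204) or 5 (0.0156).

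Pancreatitis in KO colon changed 6 genes (limma; 2798 genes had an unadjusted p under 0.05). Ogt, the O-GlcNAc transferase, rose from 18.5 ± 4.62 to 53.3 ± 14.6 FPKM (n = 5 and 4), a log2 change of 1.46 ± 0.25 (adjusted p = 0.0498). Matr3 rose by 0.62 ± 0.10 (adjusted p = 0.0287) and Wdr37 by 0.54 ± 0.09 (adjusted p = 0.0498). Areg fell from 35.0 ± 7.08 to 13.2 ± 2.71 FPKM, a log2 change of -1.33 ± 0.18 (adjusted p = 0.0118). The lipogenic genes Thrsp and Mid1ip1 fell by 0.97 ± 0.15 (adjusted p = 0.0287) and 0.64 ± 0.11 (adjusted p = 0.0498). Pecam1 was at 5.85 ± 1.29 and 4.65 ± 1.58 FPKM (adjusted p = 0.415).

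In KO colon with AP lists were called at the preset correlation of camera alone. No member of any list passed over all genes. Adjusted over the list alone, 11 of 15 mitochondrially encoded genes were higher (median 0.98, camera FDR = 3.64e-08), as were 4 of 13 enteric neuron and glia markers (median 0.57, camera FDR = 6.31e-06), including Vip at 1.39 ± 0.32, and 4 of 17 circadian genes (median 0.44, camera FDR = 0.000124). Their adjusted p = 0.432, 0.480 and 0.218 with an estimated correlation. Lower over the list alone were 9 of 20 cell cycle genes (median -0.89, camera FDR = 8.04e-08), 6 of 17 endothelial markers (median -0.44, camera FDR = 6.31e-06), with Sox18 at -0.88 ± 0.18, and 4 of 4 hemoglobin genes (median -1.87, camera FDR = 2.23e-05), which had adjusted p = 0.482, 0.324 and 0.324 with an estimated correlation.

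Interferon-stimulated genes (median -1.37, camera FDR = 7.59e-05; medians -1.99 and -2.02 without KO AP and KO sham replicate 1) and unfolded protein response genes (median -0.45, camera FDR = 0.000525) were lower too, with 0 and 3 members lower over the list alone. Adipocyte markers (median -0.67, camera FDR = 0.00384) were lower, a call that ended without KO AP replicate 1 (0.0754). Goblet cell genes (median -0.59, camera FDR = 0.0185) were lower, a call that ended without KO sham replicate 1 (0.196). Immediate early genes (median -0.31, camera FDR = 0.0112) missed without KO AP replicate 1 (0.118) or KO sham replicate 1 (0.207). T and NK cell markers (median -0.58, camera FDR = 0.0286) and macrophage markers (median -0.39, camera FDR = 0.0351) were called, but not without KO sham replicate 5 (0.878 and 0.541) or KO AP replicate 1 (0.128 and 0.123). The T and NK call also ended without KO AP replicate 4 (0.0622) or KO sham replicate 1 (0.0686), and that of macrophages without KO AP replicate 3 (0.140). The 7 lists in turn had adjusted p = 0.688, 0.324, 0.432, 0.480, 0.539, 0.910 and 0.792 with an estimated correlation.

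The count of 6 genes moved by more than 1.5 times in 17 of the 19 omissions of a single library. It was 0 without KO sham replicate 2, 69 without WT sham replicate 2, 556 without KO AP replicate 1 and 1374 without KO sham replicate 1, and lay between 1 and 11 in the rest. Areg missed without KO sham replicate 2 alone (adjusted p = 0.0520), while Thrsp, Matr3, Mid1ip1, Ogt and Wdr37 missed in 9, 10, 15, 16 and 16 of the 19. Vip passed without KO AP replicate 1 (0.0288) or KO sham replicate 1 (0.0217), and Sox18 without these (0.0441 and 0.0112) or WT sham replicate 2 (0.0463). Without the 3 libraries whose correlation with their own group was under 0.94, KO AP replicates 1 and 4 and KO sham replicate 5, it was 642.

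Clock and cytotoxic lymphocyte genes were among the genes that differed between KO and WT colon in pancreatitis. Dbp was at 93.3 ± 37.3 FPKM in KO against 7.85 ± 4.40 FPKM in WT (n = 4 and 5), a log2 difference of 3.45 ± 0.46 (adjusted p = 0.000378, limma), and the clock genes Ciart and Tef were higher at 2.59 ± 0.35 and 2.40 ± 0.26. Ccl5 was at 1.28 ± 0.833 FPKM in KO against 95.9 ± 70.9 FPKM in WT (log2 -5.08 ± 0.99, adjusted p = 0.00287), and Gzma at 0.0367 ± 0.0430 against 20.8 ± 18.5 FPKM (log2 -3.97 ± 0.85). Ido1, an interferon-induced enzyme, was at 1.59 ± 2.41 against 107 ± 93.8 FPKM (log2 -4.95 ± 1.16; -5.74 without WT AP replicate 4).

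Further falls were Ccl8 at -4.34 ± 0.67, the class I gene H2-Q7 at -4.31 ± 0.64, Gzmb at -4.31 ± 0.97 (-5.06 without WT AP replicate 4) and Iigp1 at -4.03 ± 1.12. Further rises were Mir147 at 3.38 ± 0.66, Ly6g at 3.30 ± 0.51, Car1 at 3.16 ± 0.79, Rbp2 at 2.32 ± 0.41 and Cyp2d12 at 2.29 ± 0.64. H2-Q7 and Ly6g have close relatives and Mir147 overlaps AA467197, so their levels are uncertain. Mature neutrophil genes as a list were not higher (-0.21, exact permutation p = 0.492). Iigp1 missed without KO AP replicate 3 (-3.44, adjusted p = 0.0682) or 5 (0.0630) and was at -4.73 and -4.64 without KO AP and WT AP replicate 4, and Cyp2d12 missed without KO AP replicate 3 (0.0714) or 5 (0.0507) or WT AP replicate 5 (0.0511). Pecam1 was lower in KO, at 4.65 ± 1.58 against 11.1 ± 2.44 FPKM (log2 -1.11 ± 0.19, adjusted p = 0.00151).

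In colon with AP 2743 of 15001 genes changed between genotypes, 1106 higher and 1637 lower in KO, with 1045 changed at least 2-fold. On a TPM scale 2303 changed, 541 higher and 1762 lower, with the median of all genes at -0.128. The count was 1781 without WT AP replicate 2 and 1817 without WT AP replicate 3.

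Immune cell markers were lower in KO colon with AP. T and NK cell markers were lower in 17 of 18 genes, and 18 over the list alone (median -2.65, camera FDR = 3.0e-12), with Lck at -2.48 ± 0.44, Cd4 at -2.03 ± 0.38 and Cd3e at -2.62 ± 0.49. Macrophage markers were lower in 12 of 19, and 15 over the list alone (median -1.35, camera FDR = 4.05e-07), with Cx3cr1 at -1.28 ± 0.21. Interferon-stimulated genes were lower in 5 of 20 over all genes and over the list alone (median -2.07, camera FDR = 3.11e-05), with Ifi27l2a at -3.61 ± 0.74 (-2.97 without KO AP replicate 3), and the median was -2.67, -1.37 and -1.35 without KO AP replicate 1, 3 and 5. Hemoglobin genes were lower in 4 of 4 (median -2.96, camera FDR = 9.28e-06). B and plasma cell markers were lower in 4 of 18, and 5 over the list alone (median -0.55, camera FDR = 0.00796), a call that ended without KO AP replicate 4 (0.105). These 5 lists had adjusted p = 0.338, 0.338, 0.441, 0.194 and 0.480 with an estimated correlation.

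Muscle, neuronal and clock genes were higher. Smooth muscle markers were higher in 9 of 14 genes, and 10 over the list alone (median 1.29, camera FDR = 1.92e-06), with Acta2 at 1.48 ± 0.33 and Des at 1.84 ± 0.44. Enteric neuron markers were higher in 6 of 13, and 9 over the list alone (median 0.79, camera FDR = 9.28e-06). Circadian genes were higher in 10 of 17 and lower in 3 (median 0.96, camera FDR = 8.17e-05), with Per3 at 1.93 ± 0.26. Mitochondrially encoded genes had a median of 0.72 with no member passing (camera FDR = 0.00262). These 4 lists had adjusted p = 0.367, 0.367, 0.194 and 0.480 with an estimated correlation.

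Goblet cell and mucus genes were lower in 9 of 15 in KO colon with AP, and 11 over the list alone (median -1.0, camera FDR = 3.40e-05), with Spink4 at -1.61 ± 0.35 and Atoh1 at -0.91 ± 0.20. Cell cycle genes were lower in 9 of 20, and 16 over the list alone (median -0.95, camera FDR = 3.85e-06). Endothelial markers were lower in 12 of 17 and higher in 1 (median -0.68, camera FDR = 8.38e-07), with Cdh5 at -1.28 ± 0.15. Endothelial activation genes were lower in 7 of 12 (median -0.55, camera FDR = 0.00113), matrix and fibroblast markers in 8 of 19, 10 over the list alone (median -0.55, camera FDR = 0.00113) and adipocyte markers in 3 of 9, 5 over the list alone (median -0.81, camera FDR = 0.00669). These 6 lists had adjusted p = 0.194, 0.441, 0.194, 0.344, 0.394 and 0.367 with an estimated correlation. Antimicrobial genes, of which Nod2 alone was lower, had a median of -0.63 (camera FDR = 0.0371; 0.367 with an estimated correlation). That call ended on a TPM scale (0.0656) and without WT AP replicate 1 (0.0617) or 5 (0.0694) or KO AP replicate 3 (0.0729) or 5 (0.128).

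Junction genes were lower in 5 of 18 over all genes and over the list alone, among them Cgn at -0.60 ± 0.15, without a call for the list (median -0.17, camera FDR = 0.0660) except without KO AP replicate 1 (0.0327) or 3 (0.0281). Absorptive colonocyte markers were higher in 3 of 18 and lower in 1 (camera FDR = 0.238), with Slc26a3 at 1.79 ± 0.28. Enteroendocrine and tuft cell markers were lower in 3 of 13 (camera FDR = 0.122), with Chgb at -1.46 ± 0.18, called without KO AP replicate 5 (0.0227). Stem cell markers had a median of -0.03 and a mean of 0.01 (camera FDR = 0.947). Of the 18 pancreatic acinar markers 3 were measured, with Cela1 higher at 1.22 ± 0.35, which missed without KO AP replicate 3 (0.0895) or 5 (0.0865) or WT AP replicate 3 (0.0525), and no call for the list (camera FDR = 0.638). Neutrophil granule precursor genes were lower in 1 of 3, Cybb at -1.63 ± 0.33 (camera FDR = 0.0660), and called without WT AP replicate 4 (0.0256) or KO sham replicate 5 (0.0416).

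**Figure D4:**
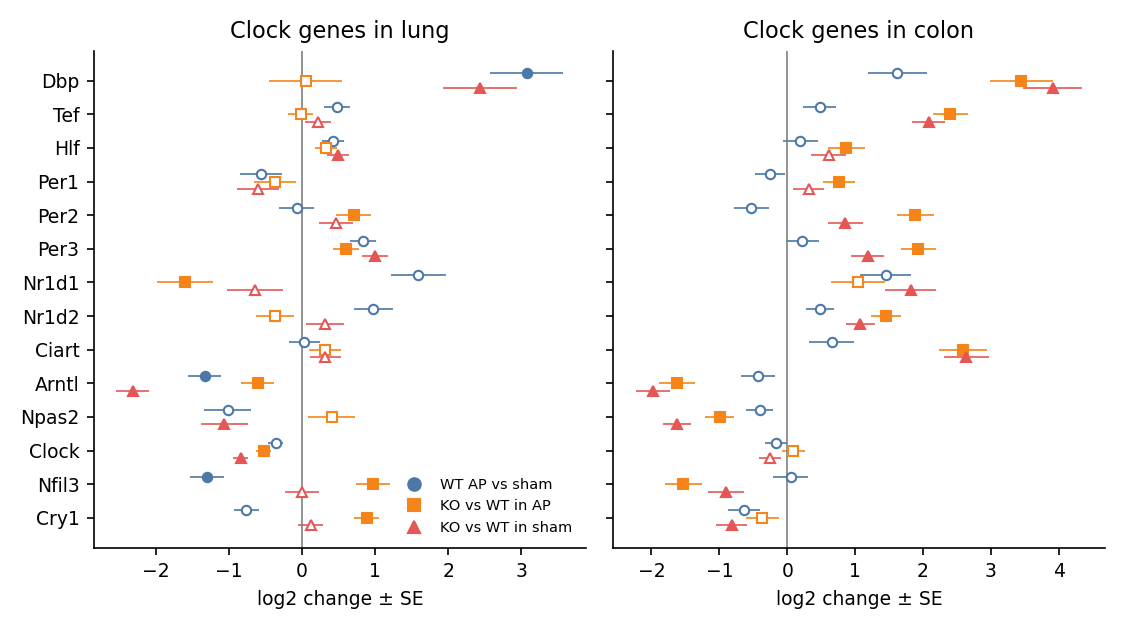
Log2 changes (horizontal axis) of 14 clock genes in lung (left) and colon (right) for AP against sham in WT and for KO against WT in AP and in sham; filled points passed at an adjusted p under 0.05, open points did not, and bars are standard errors. Dbp, Tef and Ciart lie above 2 in both colon comparisons.

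KO colon after sham operation also differed from WT, without a call for the clock list (7 higher and 4 lower of 17, median 0.40, camera FDR = 0.134; 0.646 with an estimated correlation). Dbp was at 48.7 ± 36.1 FPKM in KO and 1.68 ± 0.618 FPKM in WT (n = 5 each), a log2 difference of 3.91 ± 0.44 (adjusted p = 3.70e-05, limma), and Ciart was higher at 2.64 ± 0.33. Actg2 was higher at 2.73 ± 0.46, as were Igfbp2 at 2.33 ± 0.51 and Ckm at 2.18 ± 0.38. Ccl5 fell by 3.98 ± 0.93, Ubd by 3.09 ± 0.83 and Gzma by 3.08 ± 0.80, which became 5.2, 3.98 and 4.13 without KO sham replicate 5, and Slc34a2 fell by 3.0 ± 0.29. Pecam1 fell by 1.07 ± 0.18 (adjusted p = 0.000553).

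In colon sham 4704 of 15001 genes changed, 2398 higher and 2306 lower in KO, with 877 changed at least 2-fold. On a TPM scale 3932 changed, 1249 higher and 2683 lower, with the median of all genes at -0.151, and after upper quartile scaling 4702 changed, 1928 higher and 2774 lower. Between AP and sham, 543 genes were shared among those higher in KO and 915 among those lower, against 177 and 252 for independent lists. The log2 differences in AP and sham correlated across genes at a Pearson r of 0.667.

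T and NK cell markers were lower in 17 of 18 genes in colon sham over all genes and over the list alone (median -1.91, camera FDR = 8.24e-07). KO sham replicate 5 stood apart in these genes, at a mean log2 of 3.44 against 0.323 to 0.689 in the rest of its group. Smooth muscle markers were higher in 7 of 14, and 8 over the list alone (median 1.08, camera FDR = 0.000160), with Tpm2 at 1.84 ± 0.31 and Tagln at 1.74 ± 0.34. Macrophage markers were lower in 10 of 19, and 11 over the list alone (median -0.90, camera FDR = 0.000445), and fasting genes in 6 of 16 (median -0.45, camera FDR = 0.00123), with Cpt1a at -1.12 ± 0.14. These 4 lists had an adjusted p = 0.646 with an estimated correlation.

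Lower as well, at smaller sizes, were endothelial markers in 8 of 17 (median -0.21, camera FDR = 0.0185), junction genes in 7 of 18 with 1 higher, 8 lower over the list alone (median -0.30, camera FDR = 0.0433), acute phase proteins in 6 of 13 (median -0.73, camera FDR = 0.0433), B and plasma cell markers in 3 of 18 (median -0.63, camera FDR = 0.0433) and matrix and fibroblast markers in 7 of 19 (median -0.19, camera FDR = 0.0487). Cell cycle genes were higher in 2 of 20 (median 0.54, camera FDR = 0.0487). With an estimated correlation the adjusted p = 0.744 for cell cycle genes and 0.646 for the other 5. All 6 calls ended without a single library, WT sham replicate 2 for every list but B and plasma cell markers, at camera FDR of 0.0614, 0.154, 0.154, 0.0843 and 0.197 in the order given, and WT sham replicate 4 for B and plasma cell markers (0.146). Junction genes also missed without KO sham replicate 3 (0.0662), acute phase proteins without KO sham replicate 1 (0.0763) or 3 (0.0838), and B and plasma cell markers without KO sham replicate 2 (0.0817) or 3 (0.0806). Cell cycle genes missed in 7 of the 19 omissions and matrix markers in 8, the latter with the highest value of 0.203 without KO sham replicate 2. Those of acute phase proteins, B and plasma cell and matrix markers also ended on a TPM scale (0.0853 each) and after upper quartile scaling (0.0785 each). Of the 10 lists called, 5 remained in number without WT sham replicate 2 or without KO sham replicate 3.

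The interaction in colon had no gene past the threshold (limma; 2821 genes had an unadjusted p under 0.05). The lowest p belonged to Mid1ip1 at -0.97 ± 0.15 (adjusted p = 0.0783), Slc10a5 at 1.53 ± 0.27, the mitotic genes Bub3 at -0.96 ± 0.17 and Kifc1 at -1.94 ± 0.35, and Matr3 at 0.75 ± 0.13 (adjusted p = 0.0808 each). Pecam1 was at -0.04 ± 0.26 (adjusted p = 0.948). Without KO AP replicate 1 there were 228 calls and without KO sham replicate 1 there were 1170, with the 5 genes above at adjusted p of 0.0423 in the first case and of 0.00360 to 0.00720 in the second.

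Of 29 lists 9 were called, led by cell cycle genes, whose response to AP was lower in KO with a median of -1.51 over 20 genes, 19 of them lower over the list alone and none over all genes (camera FDR = 3.83e-11). Mitochondrially encoded genes followed with a median of 0.91 (camera FDR = 0.000101). Hemoglobin genes had a median of -1.99, with 4 of 4 lower over the list alone (camera FDR = 0.00142). Enteric neuron markers (median 0.60, camera FDR = 0.000224) and unfolded protein response genes (median -0.70, camera FDR = 0.00142) were called in every omission of a library. These 5 lists had adjusted p = 0.612, 0.641, 0.612, 0.641 and 0.612 with an estimated correlation. Across genes the responses to AP in WT and KO colon correlated at a Pearson r of -0.281.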

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

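The tests that weigh an explanation in this part were chosen after the results they bear on were seen.

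KO and WT differed in 8908 genes in lung with AP, 9393 in lung sham, 2743 in colon with AP and 4704 in colon sham. A trend with transcript length is argued against as the whole cause, since 8030, 7839, 2934 and 3459 genes were called after that trend was removed, of which 6519, 6197, 2508 and 2757 were also called before. A strain segment around Cd177 was not decided, since the median absolute change of the 20 nearest genes lay at percentile 64.8 in lung AP, 47.4 in lung sham, 77.8 in colon AP and 62.0 in colon sham of windows of 20 genes, values that the absence of a segment would give and a segment does not forbid. A library batch parallel to genotype cannot be told apart from the knockout, because 0 KO libraries in each of the 4 comparisons had a read total below the highest WT total of that comparison, and the labels give no batch.

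The mean of T and NK cell markers was lower in KO, by log2 differences of -1.97 in lung AP, -0.83 in lung sham, -2.65 in colon AP and -1.91 in colon sham (exact permutation p = 0.00794, 0.0635, 0.0159 and 0.0476), with p = 0.00794 in lung sham without KO sham replicate 4 (-1.09), and in colon sham p = 0.0556 without KO sham replicate 1, 2, 3 or 4 and 0.00794 without 5 (-2.49). From neutrophil genes this difference departed by -1.46, -1.49, -2.44 and -2.1 in that order (exact p = 0.0159, 0.00794, 0.00794 and 0.0159). This cannot decide on less blood in KO, since Cd177 is a neutrophil gene. Read from red cell genes, which differed by -1.82 in lung AP and -3.0 in colon AP, less blood remains a candidate explanation in AP, with departures of -0.158 and 0.345 (exact p = 0.476 and 0.484), and stays open in sham, at -0.208 in lung and -0.907 in colon (exact p = 0.619 and 0.254), although lung sham turned to a candidate without KO sham replicate 3 (0.0208), 4 (-0.259) or 5 (-0.0569) or WT sham replicate 2 (-0.164), 4 (-0.155) or 5 (-0.0943). Less mucosa is argued against as the whole cause in colon AP, where T and NK markers departed from colonocyte markers by -2.88 (exact p = 0.0159), although lower goblet cell (median -1.0) and higher smooth muscle (1.29) and enteric neuron genes (0.79) went with it, and stays open in colon sham at -1.88 (exact p = 0.111). Without KO sham replicate 5, less mucosa at -2.72 (exact p = 0.0238) and less blood read from red cell genes at -1.44 (p = 0.0397) were argued against in colon sham too, so both verdicts depend on that library; fewer lymphocytes by genotype was not tested apart from these.

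In 26 of 158 groups tested, a single library stood apart from the rest by a gap that was a large share of the group's range, where chance gives about 1 in 20. In 4 of them the other libraries were all at 0, which gives a ratio of 1 at any value, and without the 21 groups with a mean under 1 FPKM the number was 19 of 137. WT sham replicate 2 of colon had 22675 genes above 0 (gap over range 0.800), the lowest correlation with its group (0.885) and 4727 FPKM of Car1 (0.986). It also had 19.1 FPKM of Ogt (0.719) and 0.110 FPKM of Elane against 0 (1). Correlation with the own group was also lowest, by gaps of 0.860 and 0.915, in KO AP replicate 3 and WT AP replicate 4 of lung. That WT AP library held 11.4% mitochondrially encoded FPKM against 5.13% to 6.21% (0.827), a T and NK marker mean of 2.25 (0.715), 199 FPKM of Pecam1 (0.845) and 121 FPKM of Lyve1 (0.758). KO sham replicate 4 of lung held 6.21 FPKM of Padi4 (0.822), with gaps of 0.983 for Mpo and 0.941 for Elane. KO sham replicate 5 of lung held 1181 FPKM of Retnla (0.809).

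KO sham replicate 5 of colon had a T and NK marker mean of 3.44 against 0.323 to 0.689 (gap over range 0.882). In the same library Ccl5 was at 168 FPKM (0.990), Ido1 at 273 FPKM (0.979), Gzma at 41.8 FPKM (0.993) and Elane at 0.123 FPKM against 0 (1). KO AP replicate 4 of colon held 17.3 FPKM of Areg (0.911), 5.2 FPKM of Ido1 (0.900) and 0.0196 FPKM of Padi4 against 0 (1). Ogt was lowest in KO AP replicate 1 of colon, at 31.7 FPKM (0.830). Padi4 was highest in WT sham replicate 3 of colon, at 0.260 FPKM (0.712), and Elane in WT AP replicate 2, at 0.0311 FPKM against 0 (1).

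The interaction in lung called 16 lists by limma's camera at the preset correlation and none with an estimated one (adjusted p from 0.234 to 0.403 for these lists). The medians were -1.36 for mature neutrophil, -0.65 for neutrophil granule precursor, -0.34 for cytokine, -0.88 for interferon-stimulated, -0.55 for cell cycle, -1.12 for T and NK cell, -0.96 for B and plasma cell, -0.73 for macrophage, -0.47 for matrix and fibroblast, -0.56 for unfolded protein response, -1.31 for hemoglobin and -0.47 for alveolar macrophage genes. They were 0.24 for glucocorticoid-responsive, 0.49 for immediate early, 0.39 for fasting and 0.55 for club and ciliated cell genes. Without KO sham replicate 4 the granule precursor (camera FDR = 0.0936), cytokine (0.0768) and club cell (0.0823) calls ended, and without KO sham replicate 1 those of the unfolded protein response (0.0594) and glucocorticoid-responsive genes (0.146). The glucocorticoid call also ended without WT AP replicate 2 (0.0687) or 3 (0.0526), KO AP replicate 5 (0.125) or WT sham replicate 5 (0.0704). That of hemoglobin ended without the low-correlation libraries (0.0721). Of lists not called with all libraries, cardiac muscle genes were called in 5 of 20 omissions, mitochondrially encoded in 3, acute phase, endothelial activation and alveolar type 1 in 2 each, and endothelial, adipocyte and alveolar type 2 in 1 each, lowest at 8.86e-05 for alveolar type 1 without KO sham replicate 1.

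The interaction in colon called 9 lists at the preset correlation and none with an estimated one (adjusted p from 0.612 to 0.746 for these lists). The medians were -1.47 for interferon-stimulated, 0.37 for circadian, 0.34 for fasting, -1.51 for cell cycle, -0.70 for unfolded protein response, -1.99 for hemoglobin, 0.91 for mitochondrially encoded, -0.63 for goblet cell and 0.60 for enteric neuron genes. The interferon call (camera FDR = 0.00790) ended without KO AP replicate 3 (median -0.83, 0.116) or 5 (-0.81, 0.104), with medians of -2.11 and -2.1 without KO AP and KO sham replicate 1, the circadian call (0.0199) without KO AP replicate 3 (0.0640) and the fasting call (0.0113) without KO AP replicate 1 (0.0638) or WT sham replicate 2 (0.0976), and without the low-correlation libraries (0.279). The goblet cell call (0.0327) ended without WT AP replicate 4 (0.107), KO AP replicate 3 (0.0615) or 5 (0.0657), KO sham replicate 1 (0.179) or WT sham replicate 4 (0.0568). Of lists not called with all libraries, immediate early genes (0.0508) were called in 10 of 19 omissions, glucocorticoid-responsive genes (0.0537) in 8 and T and NK cell (0.0842) and endothelial markers (0.0811) in 5 each. The lowest values were 0.00814 without KO sham replicate 2, 0.0264 without WT AP replicate 5, 0.000918 without WT AP replicate 4 and 0.00650 without KO AP replicate 5. Cytokine (0.0177) and macrophage genes (0.0377) were called without WT AP replicate 4.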

How the results depend on the processing

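The length correction and the omission of low-correlation libraries were chosen after the data were seen, and the other alternatives were planned. For each changed count the cause was not tested, except that a fold minimum can only lower it.

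In lung, the number of genes changed by AP in WT was 13 and became 1 with no filter on low values, 1 on a TPM scale, 1640 with arrayWeights, 117 with only the compared groups in the fit, 6 at 2-fold or more and 35 without the low-correlation libraries. In KO it was 2 and became 5 with no filter, 1 at 5 FPKM or more, 4 on a TPM scale, 15 with arrayWeights, 0 with only the compared groups, 8 after the length correction and 31 without the low-correlation libraries. KO against WT fell from 8908 to 2298 genes in AP and from 9393 to 2582 in sham at 2-fold or more. The interaction went from 0 genes to 1 with a pseudocount of 0.1, 307 with arrayWeights and 1 without the low-correlation libraries. Lists called in lung sham went from 5 to 10 with no filter, 3 at 5 FPKM or more, 8 on a TPM scale, 8 with only the compared groups, 9 after the length correction and 8 without the low-correlation libraries. Lists called for AP in KO lung went from 23 to 10 without the low-correlation libraries. An estimated correlation left 1 list, for AP in KO, and 0 in each of the other 4 lung comparisons.

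In colon, the number of genes changed by AP in WT was 0 and became 2 with no filter and 4 with arrayWeights, where lists went from 6 to 3. In KO it was 6 and became 3 at 5 FPKM or more, 3 on a TPM scale, 1026 with arrayWeights, 0 with only the compared groups, 2 at 2-fold or more, 1 after the length correction and 642 without the low-correlation libraries. KO against WT in AP went from 2743 genes to 1823 at 5 FPKM or more, 4360 with arrayWeights and 1045 at 2-fold or more, and in sham from 4704 to 877 at 2-fold or more. Lists called in colon sham went from 10 to 4 with arrayWeights. The interaction went from 0 genes to 2 with no filter, 1884 with arrayWeights and 250 without the low-correlation libraries, and its lists from 9 to 18 with no filter. An estimated correlation left 0 lists in each of the 5 colon comparisons.

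Same-numbered libraries of different groups did not deviate together, with a mean correlation of -0.0169 over 30 pairs in lung, 6 of them over 0.1, and of -0.0713 over 27 pairs in colon, 7 of them over 0.1, so the numbers do not pair the samples. With the replicate block the genes changed by AP were 8 in WT lung, 1 in KO lung and 0 in KO colon, and the block moved no other count by over 1.5 times.

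Leaving out each library in turn gave 0 to 20 genes and 9 to 13 lists for AP in WT lung, 1 to 229 genes and 15 to 23 lists for AP in KO lung, 8038 to 9513 genes and 10 to 14 lists for KO against WT in AP, 8596 to 9789 genes and 2 to 7 lists in sham, and 0 to 2 genes and 13 to 19 lists for the interaction. In colon the ranges were 0 to 1 genes and 3 to 9 lists for AP in WT, 0 to 1374 genes and 9 to 16 lists for AP in KO, 1781 to 3291 genes and 15 to 19 lists for KO against WT in AP, 3473 to 5257 genes and 5 to 10 lists in sham, and 0 to 1170 genes and 7 to 12 lists for the interaction. Lists called in some omission but not with all libraries were 1 for AP in KO, 5 for KO against WT in AP, 5 in sham and 8 for the interaction in lung, and 7 for AP in WT, 4 in KO, 6 for KO against WT in AP, 3 in sham and 6 for the interaction in colon.

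The correlation across genes of the AP responses in WT and KO ranged from -0.0687 to 0.122 in lung and from -0.375 to -0.213 in colon. Cd177 in AP minus sham of WT ranged from 0.929 to 1.57 FPKM in lung and from 13.5 to 20.2 in colon.

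No named gene changed direction while passing. Over the omissions of a library, calls of named genes stayed as they were in 3048 results, were lost in 189, gained in 37 and changed sign without passing in 12. Calls lost and gained were 16 and 0 on a TPM scale, 15 and 2 with no filter, 12 and 0 with the replicate block, 9 and 2 after the length correction, 9 and 1 with only the compared groups, 4 and 0 after upper quartile scaling, 3 and 0 with a pseudocount of 0.1, 2 and 0 at 5 FPKM or more, 2 and 8 without the low-correlation libraries and 1 and 28 with arrayWeights. Such signs also changed in 3 results without the low-correlation libraries, 2 after upper quartile scaling and 1 each with a pseudocount of 0.1, a TPM scale and the length correction. Mpo and Elane lay below the filter, and the fit of only the compared groups was not run for the interaction. Upper quartile scaling moved no count by over 1.5 times.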

Other observations

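The NRF2, clock and split tests of this part were chosen after the results they bear on were seen.

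Many antioxidant and detoxification genes were higher in KO beyond those named. In a list of 27 targets of NRF2, the transcription factor of the oxidative stress response, 22 were higher and 0 lower in lung with AP, with a median log2 difference of 1.16. In lung sham 23 were higher and 0 lower, with a median of 1.39. Gstp1 was at 1.96 in AP and 2.22 in sham. In colon 11 were higher and 1 lower in AP, with a median of 0.63, and 13 were higher and 0 lower in sham, with a median of 0.55.

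Higher NRF2 target genes as a class may account for the rise of Gsta1, Gsta2 and Slc7a11 in lung. The median of the 27 targets lay at percentile 100 among 10000 random lists matched on expression in lung AP, lung sham and colon AP. It lay at 99.99 in colon sham. Matched on transcript length as well, it lay at 100, 100, 100 and 99.82, which argues against a trend with transcript length. Random lists ignore correlation between genes, and the batch that cannot be told apart from genotype bears on this hypothesis too.

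A shift towards the clock phase with high Dbp and low Arntl may explain the clock gene differences between KO and WT and of AP in WT lung. Collection time is not given. The test counts 15 of the 17 measured clock genes, those given a direction. In colon 0 of 11 called genes went against it in AP and 0 of 11 in sham. In lung 0 of 7 did in sham and 0 of 3 for AP in WT. The latter were Dbp, Arntl and Nfil3, and Dbp and Arntl define the shift, so the count for AP in WT cannot decide on it. In lung AP 3 of 8 did, but with 8908 of 15978 genes changed this argues only against a shift as the whole cause. Called but not counted were 2 in colon AP, 2 in lung sham and 1 in lung AP. The test first counted genes against the majority, and its direction was set after its result was seen, with the same values.

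Splits of the same libraries, 100 per count, show where chance can be excluded. It can, at 1 of the 100 splits each, for KO against WT with 8908 genes in lung AP (5293), 9393 in lung sham (5846), 2743 in colon AP (1929) and 4704 in colon sham (2760). The colon AP count was 1781 and 1817 without WT AP replicate 2 and 3 and 1915 without KO AP replicate 3, each at 1 of 33 splits (highest other 189, 190 and 5). For the 23 lists of AP in KO lung 1 of the 100 splits gave as many (highest other 20), but the count was 15 without KO sham replicate 4, 10 without the low-correlation libraries and 1 with an estimated correlation. For the 13 genes changed by AP in WT lung, 2 of the 100 splits gave as many (highest other 31), but the count moved by over 1.5 times in 10 of 20 omissions and was 0 without WT AP replicate 3 or 4 or WT sham replicate 2 or 3. Chance cannot be excluded for the lung lists of AP in WT (13; 11 splits, highest other 16), KO against WT in AP (11; 53, 18) and sham (5; 83, 18) and the interaction (16; 10, 19). Nor can it for the colon lists of AP in WT (6; 93, 16) and KO (13; 17, 16), KO against WT in AP (16; 7, 19) and sham (10; 47, 17) and the interaction (9; 53, 16). Among genes it cannot for AP in KO lung (2; 30, 2731) and KO colon (6; 18, 3229). Where no gene was called, as many in all 100 splits decides nothing, with a highest other of 10 for AP in WT colon and of 946 and 2 for the interaction in lung and colon. Splits with 2731, 3229 and 946 calls point to a structure of the samples, whose source was not tested.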
